A study of Mus musculus with 4 samples.

How the data were processed

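Livers of mice whose bile duct had been ligated were compared between wild type and Mertk knockout. From each liver preparation, RNA and open chromatin were read from the same nuclei with the 10x Genomics Multiome assay. In this assay a transposase cuts accessible DNA inside intact nuclei (ATAC), and droplet barcodes then tag the DNA fragments and the RNA of each nucleus. Per the labels' protocols, frozen liver was homogenised in detergent, nuclei were cleaned on a density gradient, and 10000 nuclei per sample were aimed for. Sequencing used paired 150 bp reads, per the labels. Each genotype had 1 RNA library and 1 ATAC library. The labels do not say how many animals stand behind a library, nor their sex or the time after ligation.

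Per the file headers of the peak lists, the authors ran cellranger-arc 2.0.2 against mm10. Each list has its own run identifier, so peaks were called per library. The settings of the peak caller are not given in the sources used here. The deposited peak lists hold positions alone, with no height, score or p-value. A deposited annotation assigns each peak to 1 or more genes as a promoter or distal peak, or calls it intergenic. The deposited per-barcode tables hold raw counts per barcode: reads, unique molecular identifiers (UMIs, 1 per captured RNA molecule), genes, ATAC fragments, and fragments at transcription start sites or in peaks. These counts were not normalised by the authors, judging from the values, which are whole numbers. The tables also mark which barcodes were called nuclei. A matrix of genes by nuclei was not used here, so neither cell clusters nor expression of single genes could be examined, and gene-level results come from ATAC peaks.

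Peaks on chromosomes 1 to 19, X and Y were kept, which left out 43 wild-type and 44 knockout peaks on other contigs. A peak was called shared if it overlapped a peak of the other library by at least 1 bp. The accessible length of a gene is the summed length of the peaks that the authors' annotation assigns to it as promoter or distal. For genes with a mean over both libraries of at least 2 kb, the log2 ratio of knockout to wild-type accessible length was taken with a pseudocount of 1 kb on both sides. It was then centred by subtracting its median over these genes, 0.39. A gene at or beyond 1 or -1 was counted as higher or lower, which is a rule of size and not a test. Because peaks were called separately, such sums move with how much was called in a library. Called peaks covered 61.8 Mb in the wild-type library and 91.3 Mb in the knockout library, with mean widths of 855 and 859 bp. Gene coordinates are those of the RefSeq annotation of GRCm38, the assembly behind mm10.

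There were 20 gene lists: markers of 10 cell types of liver and blood, and 10 lists of pathways and controls. They held 425 distinct genes, of which 411 had a peak and 314 reached the 2 kb minimum. A list's median was placed among the medians of 10000 random lists of the same size, drawn from genes matched on mean accessible length in 20 bins. A list outside the 2.5 to 97.5 percentile range was said to stand apart, and about 1 of 20 lists would do so by chance. The genes named in the text follow a rule: Mertk; the 12 lowest and 12 highest ratios, without predicted or clone-named genes; in each list the 4 members with the largest absolute ratio and any member with a promoter peak in 1 library alone; and the genes of the 5 widest promoter peaks found in 1 library alone. Some genes that the rule takes are not reported here. A tie at the upper end brought 13 genes in place of 12. The lists, the naming rule, the thresholds and 19 alternatives were fixed before the data were examined, where 1 setting can count for several kinds of result. Genes named outside the rule are marked as chosen after their values were seen.

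With 1 library per genotype there is no replicate, so no test between genotypes, no p-value and no leave-one-out analysis was possible. All differences describe these libraries. Shares of nuclei carry exact (Clopper-Pearson) 95% intervals that cover counting error only. Medians over all called nuclei of a library are given with quartiles. No doublet caller was run, since that needs counts per gene, so droplets that hold more than 1 nucleus may remain among the called nuclei. How the authors treated doublets is not given in the sources used here.

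The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap code was checked against bedtools 2.31.1, with equal counts. The gene-level calculation was tested on simulated peak numbers for 14647 genes, drawn with Poisson noise around the real means, independently for each library. Of 100 genes simulated at 4-fold, 85 passed the size rule in the right direction, and of 100 at 8-fold, 100 did. These genes were drawn from those with a mean of at least 4 kb. Of 14447 simulated genes with no difference, 19.1% also lay beyond 1 or -1. Single genes with few peaks are therefore weak evidence, and weight is placed on lists and on loci with many peaks. Of 200 random lists in that simulation, 15 (7.5%) lay outside the 2.5 to 97.5 range.

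Alternatives to the overlap rule, the pseudocount, the length minimum, the centring, the use of summed length, the use of distal peaks and the filter on nuclei were run. Equal numbers of peaks were tried by keeping the widest 72302 of each library. Peak widths are nearly constant, with quartiles of 826 and 905 bp in the wild-type list and 834 and 907 bp in the knockout list. Width is therefore a poor stand-in for peak strength. A random draw of knockout peaks to the same number was added after the data were seen, as was the removal of nuclei with under 10% intronic UMIs. No reference genome sequence was used here, so base composition and motifs were not examined.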

Results

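Bile duct ligation blocks the outflow of bile and leads to cholestasis, bile duct proliferation and liver fibrosis in mice. Mertk encodes a receptor tyrosine kinase of the TAM family (Tyro3, Axl, Mertk), which macrophages use to engulf dying cells. The series asked how gene expression and open chromatin differ between wild-type and Mertk knockout livers in this model. It holds 1 RNA and 1 ATAC library per genotype, read from the same nuclei, with no replicates. The wild-type preparation gave 271814475 RNA reads and 183119652 ATAC read pairs, the knockout preparation 210455798 and 222578224. Called nuclei numbered 5828 in the wild-type and 5339 in the knockout library, against the 10000 aimed for. They held 31798452 UMIs and 40858512 ATAC fragments in the wild-type library, and 11083766 UMIs and 83996145 fragments in the knockout library.

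The targeted gene was examined in both libraries. Mertk lies on chromosome 2 (mm10 coordinates 128698915 to 128803162), and the authors' annotation assigned 10 wild-type and 13 knockout peaks to it. A promoter peak was present in the wild-type library at 128698195 to 128699084 and in the knockout library at 128698350 to 128699122. In each library 6 of the Mertk peaks overlapped a peak of the other. Accessible length was 8.63 kb in the wild-type and 10.9 kb in the knockout library, a centred log2 ratio of -0.09. The labels do not describe the deleted part of the gene, and open chromatin at a promoter can persist at a disrupted allele, so these peaks do not check the genotype.

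The first comparison concerns the whole set of open regions. The knockout library had 1.47 times as many peaks as the wild-type library, 106319 against 72302. The promoters were largely common to both genotypes: 93.5% of 14691 wild-type promoter peaks and 78.9% of 17419 knockout promoter peaks were shared. Distal peaks differed more. Of 57035 wild-type distal peaks 67.1% were shared, and of 87769 knockout distal peaks 43.7%. In all, 19983 peaks were found in the wild-type library alone and 53918 in the knockout library alone. A promoter peak was present in both libraries for 14297 genes, in the wild-type library alone for 557 and in the knockout library alone for 2709. The nuclei behind the knockout list held 2.06 times as many ATAC fragments. A larger share of them fell in peaks, 46.0% against 33.7%, but each library was counted in its own peaks. The knockout peaks cover 91.3 Mb against 61.8 Mb, so these shares are not measured over like regions.

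**Figure D1:**
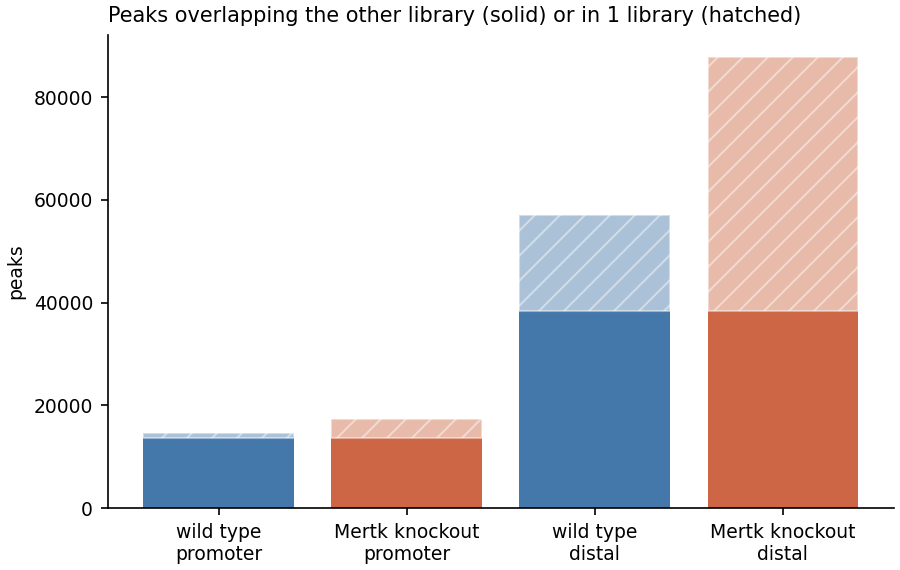
Number of promoter and distal peaks in the wild-type and Mertk knockout libraries, split into peaks that overlap a peak of the other library (solid) and peaks of 1 library alone (hatched). Most of the surplus in the knockout library is distal, with 49403 distal peaks in that library alone against 18739 in the wild-type library alone.

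The widest promoter peaks found in the wild-type library alone belonged to Sh3pxd2a (chromosome 19, 47465314 to 47466849), Pou2f1, a gene of an octamer-binding transcription factor (chromosome 1, 165934203 to 165935506), and the predicted or non-coding genes Gm1965, 4930413E15Rik and Gm16234. In the knockout library alone they included those of Acoxl (chromosome 2, 127854325 to 127855505), 8430437L04Rik, A630001G21Rik and Gm45470.

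The next comparison asked which cell types' genes differ in accessibility. Hepatocyte markers had more peaks in the knockout library, 157 against 39 in the wild-type library. Of the 20 hepatocyte markers, 7 had peaks in the knockout library and none in the wild-type library, and a promoter peak was found for 5 of the 20 in the wild-type library against all 20 in the knockout library. Markers of stellate cells and fibroblasts, the matrix-producing cells of the liver, had the same direction. Markers of neutrophils, which are short-lived white blood cells, had a median below those of random gene lists, though with about the same accessible length in total, 53.0 kb in the wild-type and 53.6 kb in the knockout library. Other blood cell markers had medians below that of the median gene but within the random range.

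Among hepatocyte markers, 12 of 18 measured members were higher in the knockout library by the size rule, 6 lay between and 0 were lower. The list had a median log2 ratio of 1.26, at percentile 100 of random lists. Alb, the gene of serum albumin (chromosome 5, 90460870 to 90476602), had 0 peaks in the wild-type library and 10 in the knockout library. Cps1, a urea cycle enzyme on chromosome 1 (67122426 to 67231267), had 0 and 12, and the cytochrome P450 gene Cyp3a11 had 0 and 10. Serpina1a, which encodes alpha-1 antitrypsin, had 0 and 6, and Cyp2e1 0 and 5. Apoa1 and Apob, genes of lipoprotein components, had 7 and 2 peaks in the wild-type library against 24 and 8. The gluconeogenic genes Pck1 and G6pc each had 1 wild-type peak, against 9 and 6, and Hamp, the gene of the iron hormone hepcidin, had 2 against 7. The 2 members below the median gene were Ttr, with 4 peaks against 3 and a promoter peak in the knockout library alone, and Ass1, with 7 against 5. Ass1 was chosen after its values were seen.

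Bile acid genes followed the hepatocyte list, of which they share 1 gene. All 20 measured members lay above the median gene, 8 of them past the size rule, with a median of 0.84 (percentile 99.99). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 2 wild-type and 11 knockout peaks. The bile salt export pump Abcb11 had 0 and 7, the uptake transporter Slco1b2 0 and 9, and the conjugating enzymes Baat and Slc27a5 0 and 9 and 0 and 7. The uptake transporter Slc10a1 had 2 and 6. Lipid and cholesterol genes had a median of 0.80 (percentile 100), with 8 of 24 higher and 0 lower. Ppara, a fatty-acid sensing nuclear receptor, had 4 and 22 peaks. Counted over promoter peaks alone, the lipid list lay at percentile 85.4, inside the random range.

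Stellate cell and fibroblast markers had a median of 1.14 (percentile 100), with 7 of 13 higher and 0 lower. The fibrillar collagen genes Col1a1 and Col1a2 each had 1 peak in the wild-type library and 9 and 12 in the knockout library. Reln had 1 and 13, Des, the gene of the intermediate filament desmin, 0 and 5, Dcn 4 and 13 and Pdgfrb 1 and 5. The wider extracellular matrix list, which shares 3 genes with this one, had a median of 0.27 (percentile 92.7), with 7 of 23 higher. Its promoter peaks in 1 library alone were 11 in the knockout library, including Loxl1, Mmp14, Bgn and Lamb1, and 2 in the wild-type library, Mmp13 and Vcan. Over all genes the knockout library led in a like way, with 2709 against 557. Mmp13, a collagenase gene, had 3 wild-type peaks and 0 knockout peaks. TGF-beta signalling genes lay near the median gene, at 0.07 (percentile 71.0), though Ltbp1 had 7 and 22 peaks.

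Neutrophil markers had a median of -0.52 (percentile 0.82) over 8 measured genes, of which 1 passed the size rule. Ltf, the gene of lactoferrin, had 6 wild-type and 3 knockout peaks, Csf3r, the receptor for granulocyte colony-stimulating factor, 11 and 7, and Cebpe, a granulocyte transcription factor, 8 and 6. Other members went the other way: S100a9 and Cxcr2, chosen after their values were seen, each had 3 and 5 peaks, and the promoter peaks in 1 library alone, of Camp and Elane, were in the knockout library. With no length minimum, the list lay at percentile 41.6. Monocyte and macrophage markers had a median of -0.33 (percentile 2.56), with 4 of 17 lower and 0 higher. The chemokine receptor gene Ccr2 had 9 and 5 peaks, the integrin genes Itgam and Itgax 15 and 8 and 7 and 3, and Gpnmb 6 and 4. Of the 17, 3 lay above the median gene, including Ly6c2 (2 and 4) and Cd9 (7 and 11), chosen after their values were seen. Kupffer cells are the resident macrophages of the liver, and their markers had a median of -0.25 (percentile 7.64). Vsig4, a complement receptor gene of Kupffer cells on chromosome X (96247201 to 96293438), had 8 wild-type peaks and 1 knockout peak, and its promoter peak was in the wild-type library alone. Folr2 had 5 and 3 peaks and Timd4, a phosphatidylserine receptor gene, 12 and 9. Of the 12 measured Kupffer markers, 2 lay above the median gene. These were Clec4f (2 and 5 peaks) and Fcna (3 and 5), both chosen after their values were seen. All listed Kupffer markers together had 89 peaks in each library. Without centring, the medians of the Kupffer and monocyte lists were 0.14 and 0.06, so they were low only relative to the general surplus of knockout peaks, while that of neutrophils stayed below 0 at -0.13.

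**Figure D2:**
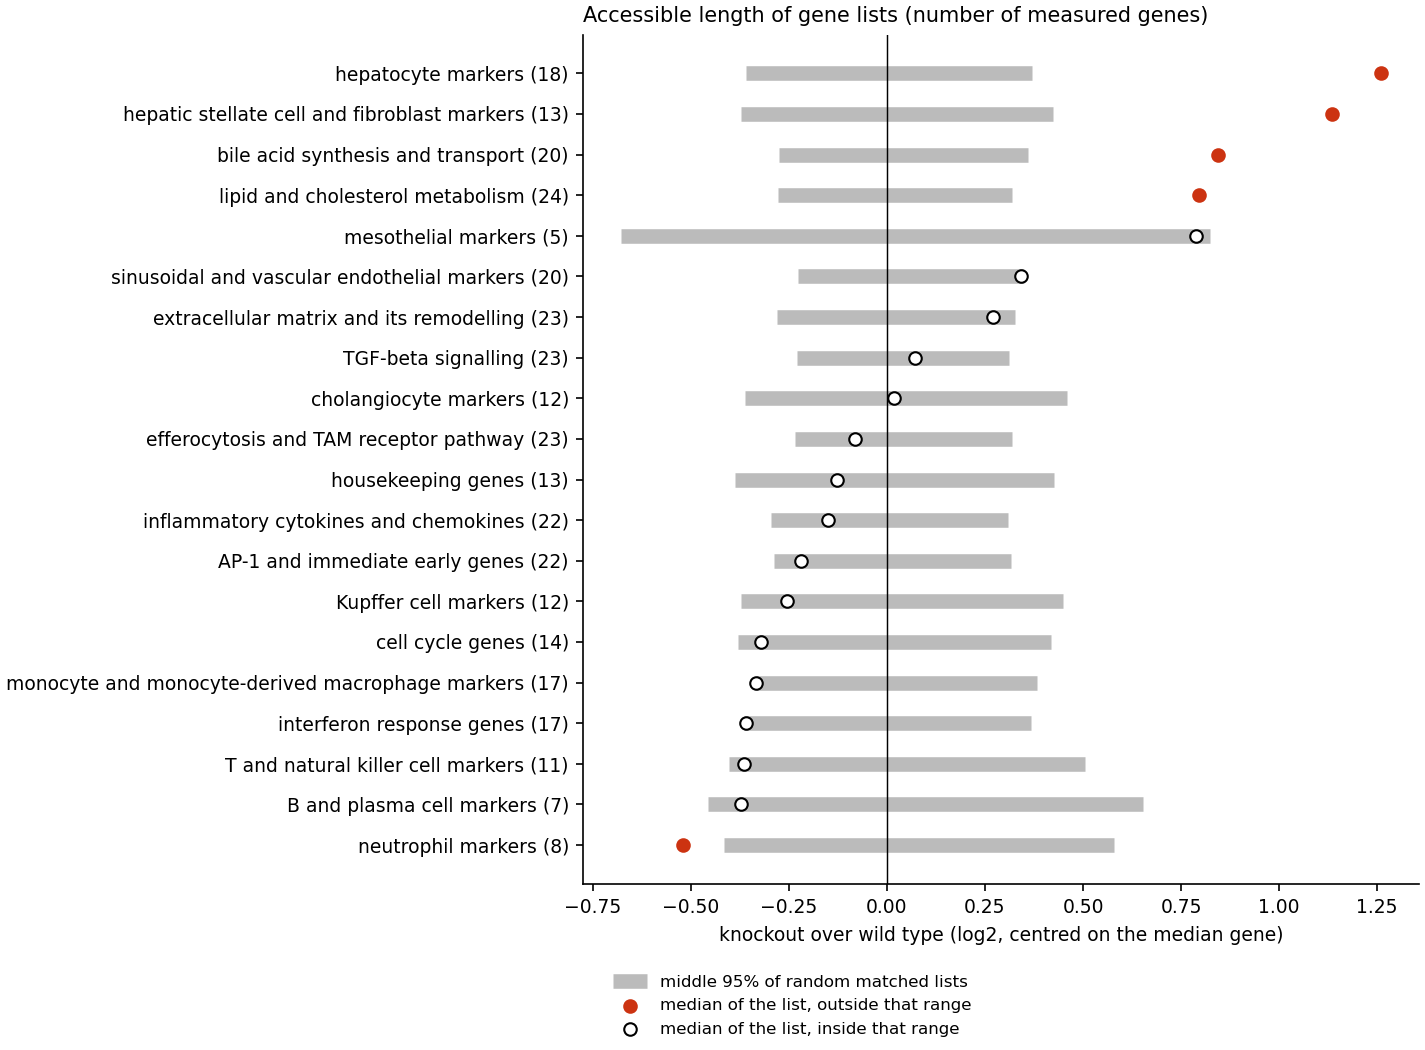
Median centred log2 ratio of accessible length, knockout over wild type, of each of the 20 gene lists (points), with the range that holds the middle 95% of 10000 random lists matched on accessible length (grey bars). Hepatocyte, stellate, bile acid and lipid lists lie above their ranges, from 0.80 to 1.26, and neutrophil markers lie below theirs at -0.52.

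T and natural killer cell markers had a median of -0.36 (percentile 4.90), with promoter peaks in the wild-type library alone for 5 genes, including the cytotoxic granule genes Nkg7 and Gzmb. Ncr1, an activating receptor of natural killer cells, had 6 and 2 peaks. B and plasma cell markers had a median of -0.37 (percentile 9.49) over 7 genes. Interferon response genes had a median of -0.36 (percentile 2.83), with 2 of 17 lower and 1 higher. Ifit3 had 7 and 3 peaks and Ifi44 4 and 2. Cytokine and chemokine genes had -0.15 (percentile 13.0), with Il18 at 7 and 3 and Cxcl12 at 5 and 16. Cell cycle genes had -0.32 (percentile 5.19), AP-1 and immediate early genes -0.22 (percentile 6.27) and housekeeping genes -0.13 (percentile 27.0). Endothelial markers had 0.34 (percentile 97.2), with 1 of 20 past the size rule, Flt4, at 3 and 14 peaks. Mesothelial markers had 0.79 over 5 genes (percentile 96.7), and 3 of the 10 listed had no peak in either library. Of the 5, Upk1b went the other way, with 4 and 3 peaks. Without centring, the negative medians in this paragraph were above 0, at 0.02 to 0.27.

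Cholangiocyte markers, which mark the bile duct cells that proliferate after ligation, had a median of 0.02 (percentile 52.0), with 4 of 12 higher and 0 lower. They included Pkhd1 (0 and 9 peaks), Onecut1 (2 and 9) and Bicc1 (3 and 10). Spp1, which encodes osteopontin, had 5 and 6 peaks, with a promoter peak in the wild-type library alone. The efferocytosis and TAM receptor list, which holds Mertk's own pathway, also lay in the middle, at -0.08 (percentile 19.8). Of its 23 measured genes 1 was higher by the size rule, Adgrb1, a phosphatidylserine receptor gene with 0 and 8 peaks. The bridging ligand gene Pros1 had 3 and 8 peaks, Dock1 12 and 30, and Dock2, its relative in blood cells, 15 and 11.

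**Figure D3:**
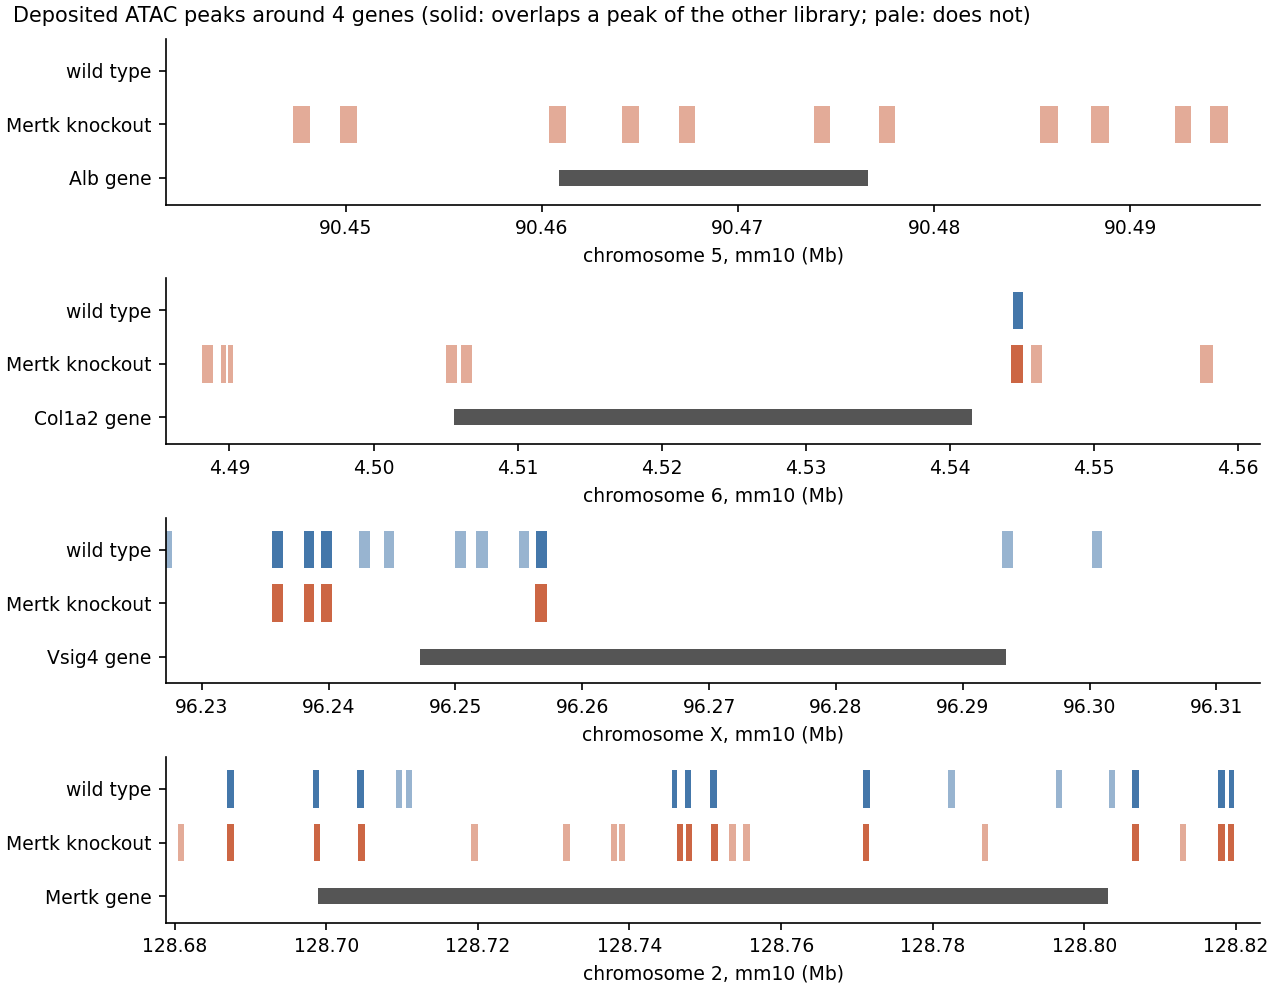
Deposited ATAC peaks of both libraries within 20 kb of Alb, Col1a2, Vsig4 and Mertk (mm10, Mb), solid where a peak overlaps a peak of the other library and pale where it does not, with the gene as a grey bar. In these windows the wild-type and knockout libraries have 0 and 11 peaks around Alb, 1 and 8 around Col1a2, 12 and 4 around Vsig4, and 15 and 19 around Mertk.

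Gene by gene, 1514 of 14692 measured genes (10.3%) were higher in the knockout library by the size rule and 600 (4.08%) were lower, so 71.6% of those past the rule were higher. The median gene had a 1.31-fold ratio in favour of the knockout library, and this was removed by centring. Without centring the numbers were 2884 higher and 197 lower, 93.6% higher. Genes with at least 5 peaks in 1 library and 0 in the other numbered 445 in favour of the knockout library and 14 in favour of the wild-type library. In the simulation of genes with no difference 19.1% passed the rule in either direction. Each library was drawn independently there, while the real libraries shared many peaks, so the simulated rate may be too high for these data. With no replicate the real rate is unknown, so the numbers above do not count genes that differ between genotypes.

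The highest ratios were at genes listed at 0 in the wild-type library. Pde3a, a cyclic nucleotide phosphodiesterase gene (chromosome 6, 141249269 to 141506862), had 23 knockout peaks, of which 15 were also assigned to another gene. Aldh1a1, which makes retinoic acid, and Gc, which encodes the vitamin D-binding protein secreted by hepatocytes, had 20 each. Lmo7 had 19, Pcsk6 and Zfp385b 17 each, and Ppp2r2b, Ly6l and Cccd201 16 each. Sntg1 had 15, as did Ntm and Them7. Among the lowest ratios, Fcrls, an Fc receptor-like gene (chromosome 3, 87250736 to 87263765), had 6 wild-type peaks and 0 knockout peaks, and Gpr174, Fmo9 and the natural killer receptor gene Klrk1 had 5 and 0. Cd226, an adhesion receptor of T and natural killer cells, had 9 and 1 (log2 ratio -2.65), Tnfsf8, the gene of the CD30 ligand, 13 and 2 (-2.54), and Sirpb1a 9 and 1 (-2.53). The other low genes were Vsig4 (-2.46), H2al2a (-2.32), Runx2os2 (-2.28), Glcci1 (-2.23) and Mettl21a (-2.21). A peak can be assigned to several neighbouring genes. Of the 25 lowest and highest genes, 12 had no peak that was also assigned to another gene, 12 shared some, and Runx2os2 shared all of its peaks. Pde3a, Ly6l, Cccd201, Gpr174, Fmo9, Sirpb1a and H2al2a had no promoter peak in either library.

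The nuclei themselves also differed between the preparations. Nuclei of the wild-type library were rich in RNA and poor in ATAC fragments, and those of the knockout library the reverse. The median nucleus had 3769 UMIs (quartiles 2197 and 6197) in the wild-type library and 1232 (483.5 and 2723.5) in the knockout library, a 3.06-fold difference. The knockout nuclei fell into a low and a high group by UMIs, and 45.9% of them (2450 of 5339, interval 44.5% to 47.2%) had under 1000 UMIs, against 6.40% in the wild-type library (373 of 5828, interval 5.79% to 7.06%). Median ATAC fragments were 4950.5 (quartiles 2126 and 9206.5) in the wild-type and 8771 (4329.5 and 17275) in the knockout library. The median share of a nucleus's fragments in peaks was 34.6% (24.8% and 40.3%) and 51.7% (44.3% and 56.8%), each in the library's own peak list. Median shares of fragments at transcription start sites were 27.2% (21.9% and 30.6%) and 34.7% (31.0% and 37.6%), and of mitochondrial reads among ATAC reads 0.931% (0.490% and 1.91%) and 2.13% (1.26% and 3.98%). Among barcodes with at least 500 UMIs and 500 fragments, called or not, the order of UMIs turned, with medians of 1716 in the wild-type and 1797 in the knockout library.

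A group of called nuclei with hardly any intronic RNA was found in the wild-type library. Intronic UMIs come mostly from unspliced RNA inside the nucleus. Under 10% intronic UMIs were found in 625 of 5828 wild-type nuclei (10.7%, interval 9.94% to 11.5%) and in 1 of 5339 knockout nuclei (0.0187%, interval 0.00047% to 0.104%). In the wild-type group, a median of 14.4% of ATAC fragments lay in peaks, against 35.8% in the other nuclei. The group supplied 5.65% of the UMIs and 1.71% of the peak fragments of the wild-type nuclei. Among barcodes not called nuclei, intronic UMIs made up 9.002% in the wild-type and 23.1% in the knockout library. The 10% limit was chosen after the data were seen.

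**Figure D4:**
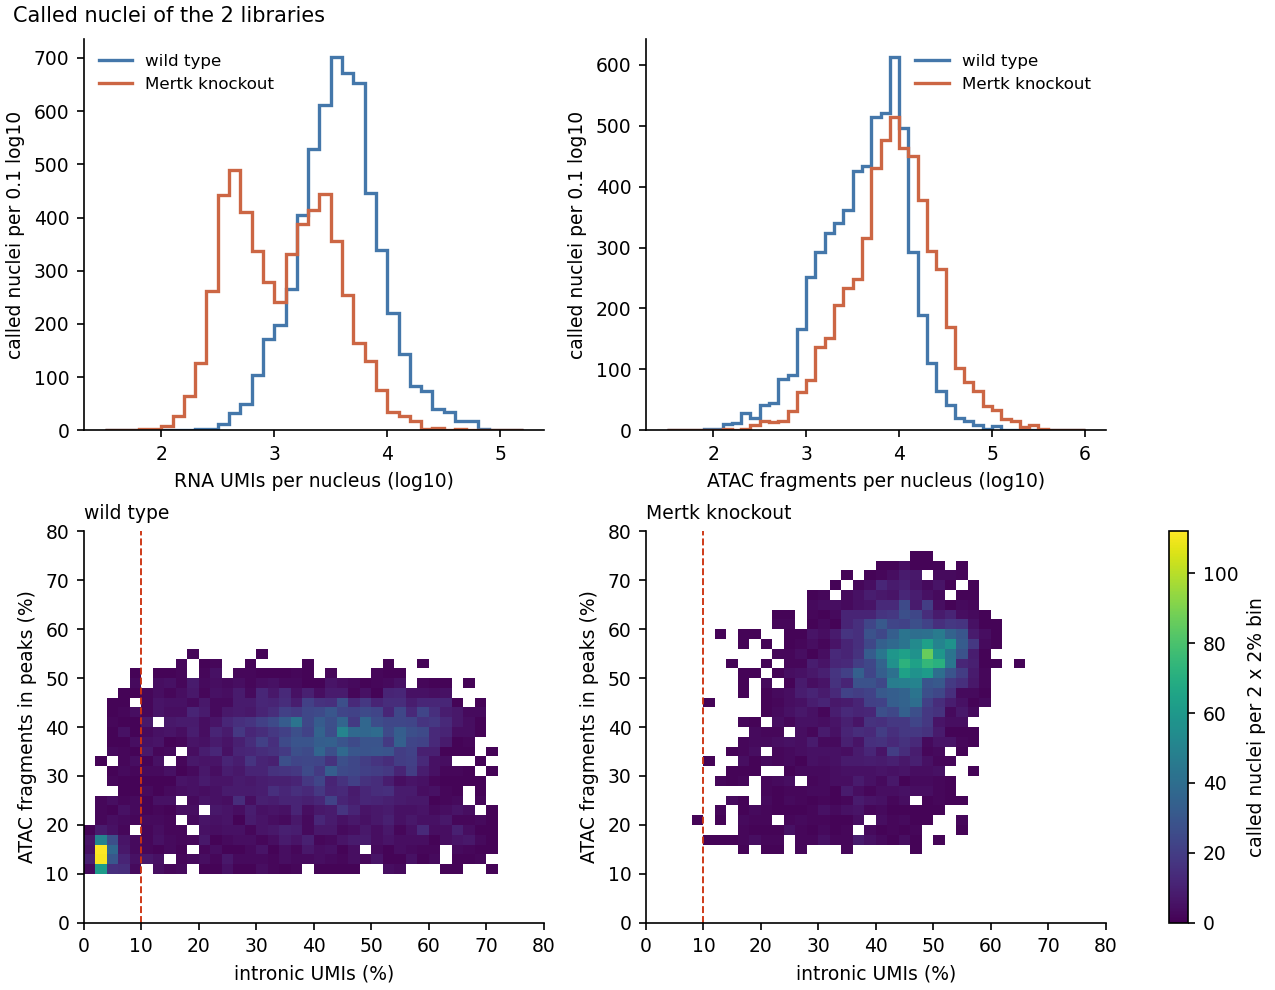
Called nuclei of both libraries: histograms of RNA UMIs and of ATAC fragments per nucleus (log10 axes), and the share of ATAC fragments in peaks (%) against the share of intronic UMIs (%), coloured by the number of nuclei per bin. The wild-type library has a dense group left of the dashed 10% line (625 nuclei, against 1 in the knockout library), and the knockout UMI histogram has 2 humps.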

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

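In the knockout RNA library, 1 barcode that was not called a nucleus held 16749287 raw reads, 7.96% of the reads of that library, and lies outside the comparisons above. Of these reads 10150 were mapped, and they gave 130 UMIs. The next such barcode of that library had 285391 reads, and the highest of the wild-type library 263881. It stands out as a signal in data that no comparison used, and no explanation for it was tested.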

How the results depend on the processing

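No paired analysis was possible because each assay has 1 library per genotype, which leaves no pairs to compare, and no replicate could be left out. Where a value moved, the cause was not tested unless the setting itself gives it. The random draw of knockout peaks and the removal of nuclei with few intronic UMIs were chosen after seeing the data. The hepatocyte, stellate and bile acid lists stood apart in the same direction under all 7 alternatives, at percentiles from 99.99, 99.95 and 99.93 up to 100. Of the 140 list values under alternatives, 122 stayed inside or outside the range as before. Of these, 8 crossed the middle of the random lists while inside the range. The direction of the cholangiocyte, Kupffer, B cell, cell cycle, efferocytosis, cytokine and housekeeping lists therefore depends on the setting. Of the 8 crossings, 5 came with promoter peaks alone, where the medians of these lists were only 0 to 0.02. Kupffer markers were at 81.0 and cell cycle genes at 93.9 with promoter peaks alone. B cell markers were at 93.6 with the random draw, over 5 measured genes.

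Sharing of wild-type peaks was 70.8% when 50% of both peaks had to overlap, 51.2% among the widest peaks and 49.4% against the random draw of knockout peaks. The last 2 follow from having fewer peaks to overlap. Sharing of knockout peaks was 48.1% and 51.1% under the 50% rule and among the widest peaks.

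Genes lower in the knockout library numbered 1043 with a pseudocount of 0.25 kb, 84 with 4 kb, 1334 with no length minimum, 197 without centring and 26 with promoter peaks alone. Genes higher numbered 468 with a pseudocount of 4 kb, 2872 with no minimum, 2884 without centring and 245 with promoter peaks alone. Of 208 values of the named genes under alternatives, 186 were alike, 20 fell short of the size rule and 2 reversed. All values that fell short or reversed came with promoter peaks alone. Among the lowest and highest genes, Aldh1a1, Lmo7 and Ntm alone stayed past the size rule there, so the others rest on distal peaks. With promoter peaks alone Tnfsf8 was at 0.039 and Runx2os2 at 0.0093, and a gene there rarely has more than 1 peak.

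With no minimum, neutrophil markers were at percentile 41.6, and with promoter peaks alone lipid genes were at 85.4 and AP-1 genes reversed to 97.8. Lists that came to stand apart were monocyte markers (2.42 with a pseudocount of 0.25 kb, 0.89 with no minimum, 1.95 by number of peaks, 0.245 among the widest peaks, 2.18 with the random draw) and interferon genes (1.45 with no minimum, 1.16 among the widest peaks, 0.74 with the random draw). Matrix genes did so at 98.5 with 4 kb, 99.97 with no minimum and 98.4 among the widest peaks, mesothelial markers at 97.8 with no minimum, and cytokine genes at 1.80 with the random draw. Among the widest peaks cell cycle genes were at 1.63 and efferocytosis genes at 2.08.

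Among called nuclei with at least 1000 UMIs and 1000 fragments, the knockout library kept 2777. Medians there were 4004 and 2580 UMIs, 5950 and 15004 fragments, and 35.3% and 51.1% of fragments in peaks, in the wild-type and knockout library. Over every barcode with at least 500 UMIs and 500 fragments there were 10243 in the wild-type library, with medians of 1716 and 1797 UMIs, 1760 and 11183.5 fragments, and 17.8% and 50.02% in peaks. Without nuclei under 10% intronic UMIs the wild-type medians were 4037 UMIs, 5678 fragments and 35.8% in peaks. ATAC fragments per nucleus and their share in the library's own peaks were higher in the knockout library in each of these settings. With fewer ATAC fragments behind the wild-type list, a locus without a wild-type peak is not shown to be closed.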

Other observations

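The gene families and windows below were picked after their values were seen, so their values only describe these libraries. All 12 measured UDP-glucuronosyltransferase genes, which make detoxifying enzymes, were higher in the knockout library by the size rule, with a median log2 ratio of 2.03. The window from 87000001 to 88000000 on chromosome 5, which holds Ugt2 and Sult1 genes, had 0 wild-type and 46 knockout peaks. Cytochrome P450 genes (Cyp1 to Cyp4) had a median of 1.77, with 17 of 31 higher, and serpin A genes 1.02, with 8 of 15 higher. Apolipoprotein genes had 0.95, with 3 of 6 higher, and complement genes 0.71, with 4 of 11 higher. No member of these families was lower. Collagen genes had 0.60, with 7 of 23 higher and 1 lower, and adenylate cyclase genes 0.73, with 3 of 10 higher. The adenylate cyclase set was matched by name and also holds the receptor gene Adcyap1r1. Aldehyde dehydrogenase genes (0.37, 4 of 16 higher) and Slco transporters (0.39, 2 of 7 higher) had smaller medians. Further windows with many knockout peaks held Ppargc1a, a coactivator of mitochondrial and gluconeogenic genes (2 wild-type and 20 knockout peaks), the pioneer factor gene Foxa1 (0 and 9), and Cdh2, which encodes N-cadherin (1 and 22).

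Several receptor families of blood cells and the interferon-induced GTPases had medians below that of the median gene. Apart from the killer cell lectin-like receptors, few of their members were past the size rule. Killer cell lectin-like receptors had a median of -1.31, with 3 of 5 lower, and C-type lectins of the Clec family -0.67, with 3 of 23 lower and 1 higher. Cd300 receptors had -0.55, with 0 of 8 lower, membrane-spanning 4A genes -0.42, with 2 of 11 lower, and Fc receptors -0.39, with 2 of 11 lower. Interferon-induced GTPases had -0.36, with 0 of 13 lower and 1 higher. Without centring, which adds 0.39 to every value, the Fc receptor and GTPase medians are no longer below 0. The window with the lowest ratio, from 65000001 to 66000000 on chromosome 6, had 33 wild-type and 15 knockout peaks and holds Hpgds, a prostaglandin D2 synthase gene, at 11 and 4. Rgs1, a regulator of chemokine receptor signalling in lymphocytes, had 21 and 12. Neighbouring family members can share peaks, so members of clustered families are not independent. Of 1664 windows of 1 Mb with at least 30 peaks, 1515 had more peaks in the knockout library and 128 in the wild-type library.

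The tests in the next paragraphs on peak numbers and on the surroundings of Mertk were written before the data were seen, and those on hepatocyte loci afterwards. The larger number of knockout peaks came with the 2 differences that a technical origin predicts. Called knockout nuclei held 2.06 times as many ATAC fragments as wild-type nuclei, and the wild-type share of fragments at transcription start sites differed from the knockout share by -4.45 percentage points, so both depth and signal over background went with the peak number. Either test could have come out the other way, but neither tells a technical origin apart from a difference in cell make-up or genotype. A difference between genotypes in the number of open regions stays untested, since each genotype is 1 library.

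Knockout alleles made in stem cells of another mouse strain can carry a flanking segment of that strain, whose variants may add or remove peaks near the gene. Within 5 Mb of Mertk, 460 of 1240 peaks (37.1%) were found in 1 library alone. That share lies at percentile 18.3 of 263 windows of 10 Mb, whose median was 42.2%, which argues against a segment visible in these peak lists. The strain of the mice and the design of the allele are not given in the sources used here.

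Peaks at hepatocyte and stellate loci that the wild-type list lacks may reflect preparation, cell make-up or genotype. The hepatocyte list lay at percentile 100 of lists matched on accessible length, so it moved more than genes of like accessible length. That percentile is itself the pattern to be explained, and the lists were not matched on peak height, which the deposited peaks lack. It therefore cannot decide whether a lower depth acting on all loci was the cause. A lower share of hepatocyte nuclei alone was taken to move the markers of other cell types alike. The stellate list exceeded the monocyte list by 1.47, while 95% of random pairs of lists differed by -0.54 to 0.55. That pair was chosen after its values were seen, and peaks called at unequal depth need not move alike in every cell type. The comparison therefore does not decide whether a lower share of hepatocyte nuclei alone was the cause. Whether hepatocyte nuclei were lost or broken during wild-type isolation cannot be told apart from the other causes: 10.7% of the called wild-type nuclei had under 10% intronic UMIs, but the genes behind those UMIs were not used here. A lower depth and a lower share of hepatocyte nuclei stay open. So do a joint shift in several cell types, a depth effect that differs by cell type, and an effect of Mertk loss, which were not tested.

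Among called nuclei with 2000 to 4000 UMIs, a range chosen after the data were seen, the median number of genes was 1657 in 1846 wild-type nuclei and 1424 in 1220 knockout nuclei. Median UMIs in that range were 2939 and 2749.5, so the wild-type nuclei were also slightly deeper. Of RNA reads in called nuclei, 88.2% were mapped in the wild-type and 78.0% in the knockout library, and of mapped reads 22.1% and 34.5% were intergenic.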
